A study of Danio rerio with 15 samples.

How the data were processed

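Zebrafish embryos were raised at 28.5 °C until 10 hours after fertilization and then at 32 °C until 27 hours, per the labels' protocols. The spinal cord region above the yolk extension was dissected, without the pronephros region for the V1 samples, dissociated with papain and sorted by fluorescence, per the labels' protocols. RNA went through 2 rounds of amplification before labelling and hybridization to the Affymetrix Zebrafish Genome Array, per the labels' protocols. The deposited values are RMA values on the log2 scale, made by the authors with Affymetrix Expression Console, per the submitters' processing notes. The log2 scale was read from the deposited values, whose range and quartiles were alike on all arrays. The versions of these programs, the chip definition and the genome build are not given in the sources used here.

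The table held 15617 probe sets on 15 arrays. A set of 115 control probe sets stayed out of the tests and of the adjustment, which left 15502. Of these, 10795 carried 1 gene symbol in the platform annotation, 135 several and 4572 none. Gene numbers were matched to current symbols, which changed 1 symbol, left 10710 as they were and found no match for 84. The probe sets with 1 symbol stood for 8793 genes. Probe sets with several or no symbol were tested but entered no gene list and are not named. Replicates are those that the labels number, 6 for V1 interneurons, 5 for all spinal neurons and 4 for trunk cells. No batch, day or clutch is named in the labels.

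Group means were fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default prior), with 12 residual degrees of freedom before moderation. Each of the 3 differences was tested with limma's two-sided moderated test, and Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets within a comparison was the threshold. Standard errors are the moderated ones. Counts are of probe sets, given again for a log2 difference of 1 or more. Probe sets above or below both other groups were counted, and set beside the count for independent lists of the same sizes, 100 simulations of unchanged groups against the V1 arrays, and fits in which the V1 arrays with odd and even numbers served different comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

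A total of 27 gene lists covered spinal neuron classes, transmitters, neuronal function, progenitors, other cell types of the trunk and general processes. Each gene entered through its probe set with the highest mean over all arrays. The 26 lists with 3 or more measured genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Calls were repeated with the correlation estimated per list. In the comparison of V1 with all neurons 5 lists were higher and 14 lower, in that of V1 with trunk 4 and 5, and in that of all neurons with trunk 10 and 7. Some genes are in several lists, such as foxd3 in the V1, dorsal and neural crest lists, gata3 in the V2, skin and pronephros lists, and shha in the progenitor and notochord lists.

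Named genes followed a rule. It took pax2a, en1b, en1a and elavl3 in every comparison, and the 10 higher and 10 lower genes with the largest difference between V1 and all neurons, or 6 and 6 in the other comparisons. These had to pass the threshold in a probe set with 1 symbol, show no overlap between the groups in any array, and reach the median of all values, 5.52, in the higher group. It added up to 3 members of each list with the largest called difference between V1 and all neurons, up to 2 between all neurons and trunk, and the members of any count of 5 or fewer. The rule gave 120 genes. The groups, tests, lists, rule and alternatives were chosen before the data were examined, except those named as later choices.

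The steps were tested on simulated data with the real arrays' means and spread and known changes. Between V1 and all neurons, 54.2%, 87.3% and 97.1% of probe sets changed by log2 differences of 0.5, 1 and 2 were called, with 9 false calls, or 5.26% of calls. Between V1 and trunk these were 46.2%, 85.4% and 100%, with 8 false calls (4.76%), and between all neurons and trunk 39.5%, 75.4% and 100%, with 8 false calls (5.52%). A simulated shift of 1 in the skin list was called (adjusted p = 9.27e-84), and 0 of 25 other lists were. The simulated noise was independent between probe sets, whereas the estimated correlation in the real lists reached 0.646 for ribosomal protein genes. The simulation therefore does not show how often lists of correlated genes are called falsely.

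Alternatives were a trended robust variance prior, fits of only the groups compared, cyclic loess, equal array medians, equal ribosomal protein means, filters on dim probe sets, array weights, the replicate number as a fixed or random block, leaving out each array in turn, a test against a log2 difference of 0.5 (limma's treat) and a threshold of 0.01. Lists were also tested with fry and with other probe sets per gene, and named genes were read from their other probe sets. Leaving out sets of arrays that stand apart in the principal components was added after seeing the data. For each comparison, 100 splits of the arrays into groups of the same sizes were counted.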

Results

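Gene expression was measured on 15 arrays of RNA from cells sorted by fluorescence from the trunk of zebrafish embryos aged 27 hours after fertilization. V1 interneurons, an inhibitory class of ventral spinal interneuron that the labels also call CiA, were sorted from a line carrying GFP under control of pax2a (6 arrays). All spinal neurons were sorted from a line carrying EGFP under control of elavl3, a gene of postmitotic neurons (5 arrays). Trunk cells, which hold spinal cord and other tissues, came from embryos for which the labels name no transgenic line (4 arrays). Control probe set AFFX-Dr-U43284-1_s_at read 10.16 to 10.76 in all-neuron arrays, 4.98 to 5.59 in V1 arrays, 8.02 and 8.16 in trunk arrays 1 and 2, and 5.63 and 5.71 in trunk arrays 3 and 4. The groups overlap in content, since V1 cells are part of all spinal neurons and spinal neurons are part of the trunk. Each array gave RMA values on the log2 scale for 15617 probe sets, of which 15502 were tested after 115 control probe sets were set aside. The median of all values was 5.52. The number of arrays limits the precision of each difference, and no detection call was used, so levels near the bottom of the scale are not known to lie above background, and a difference from such a level is one of signal only.

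Arrays of the same group resembled each other more than arrays of different groups. Across probe sets, which are not independent replicates, Pearson's r between arrays was 0.979 to 0.994 within the V1 group, 0.98 to 0.997 within the all-neuron group and 0.98 to 0.992 within the trunk group. Between V1 and all-neuron arrays it was 0.943 to 0.971, and between all-neuron and trunk arrays 0.894 to 0.95. The first principal component held 49.4% of the variance and the next 25.9%. Within the all-neuron group, skeletal muscle genes had mean levels of 7.87, 8.11 and 7.90 in arrays 1 to 3 but 6.46 and 6.65 in arrays 4 and 5. V1 arrays lay between 6.13 and 6.93 for these genes, and trunk arrays between 9.61 and 9.84.

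The first comparison asked which transcripts V1 interneurons carry at another level than spinal neurons at large. V1 arrays held more transcript of V1 transcription factors such as en1b, otpb and pax2a, and far more of globin, vessel and pigment cell genes. They held less transcript of genes that mark V2b interneurons, Kolmer-Agduhr cells and Rohon-Beard neurons, such as sox1a, gata3 and runx3. Of 15502 probe sets, 1966 were higher and 1442 lower in V1 arrays, and 521 and 332 of these differed by a log2 difference of 1 or more. Setting the mean of the ribosomal protein genes equal on every array moved the median of all probe sets to −0.57 and the split to 498 higher and 11760 lower, and differences under that scaling are read against this shift.

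The homeobox gene en1b, the marker of V1 cells, had a mean of 11.25 ± 0.24 (SD, n = 6) in V1 arrays and 9.64 ± 0.20 (n = 5) in all-neuron arrays, a 3.06-fold difference (log2 difference 1.61, SE 0.12, adjusted p = 2.78e-07). Its paralog en1a stayed near the bottom of the scale, at 2.91 ± 0.10 and 2.95 ± 0.15, and did not pass the test (−0.04, adjusted p = 0.814). pax2a, a paired-box factor of inhibitory interneurons whose control sequence drives the reporter of the V1 line, was 2.46-fold higher in V1 arrays (SE 0.20 on the log2 scale, adjusted p = 1.96e-04). Its other probe set did not pass (0.29, adjusted p = 0.0523). The homeobox gene otpb was 3.55-fold higher (1.83, SE 0.20, adjusted p = 8.57e-06). Of 14 measured V1 transcription factors 6 rose and 2 fell, the same counts when adjusted over the list alone, and those that fell were sp8b (−0.99) and foxp2 (−0.43). The list was higher as a set (median 0.36, adjusted p = 0.0398, adjusted p = 0.235 with an estimated correlation). With ribosomal protein means set equal its median was −0.20, above that of all probe sets (−0.57). The call ended without V1 array 3 (median 0.32, adjusted p = 0.0541) and without all-neuron array 1 (0.27, adjusted p = 0.0612).

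Genes of inhibitory transmission moved apart. gad2 and gad1b, which encode the enzymes that make GABA, were lower in V1 arrays by 3.10-fold (log2 difference −1.63, SE 0.18, adjusted p = 7.67e-06) and 2.46-fold (−1.30, SE 0.26, adjusted p = 1.71e-03). slc32a1, the vesicular transporter of GABA and glycine, was 1.33-fold higher at 11.15 ± 0.25 (n = 6) against 10.74 ± 0.14 (n = 5), with adjusted p = 0.0207. With ribosomal protein means set equal it stood at −0.15, above the median of all probe sets under that scaling (−0.57). Cyclic loess scaling (0.25, adjusted p = 0.143) and leaving out all-neuron array 2 (0.38, adjusted p = 0.0522) ended its call. Of 4 measured genes in this list 1 rose and 2 fell, also when adjusted over the list alone, and abat, which breaks down GABA, did not pass (−0.60, adjusted p = 0.241). Of 7 listed genes of glutamate transmission 0 were measured. The set test gave adjusted p = 0.055 with a median of −0.95, and came below the threshold without all-neuron array 1 (adjusted p = 0.0307) or without V1 array 1 (0.0458), 4 (0.0453) or 5 (0.0493).

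Some genes of other spinal neuron classes were lower in V1 arrays. Of 9 genes of V2 interneurons and Kolmer-Agduhr cells 8 fell and none rose, also when adjusted over the list alone (median −1.80, adjusted p = 5.95e-13, adjusted p = 0.0241 with an estimated correlation). The transcription factor genes sox1a (11.8-fold lower, −3.56, SE 0.20, adjusted p = 1.17e-08) and gata3 (9.34-fold lower, −3.22, SE 0.16, adjusted p = 4.81e-09) led this list, with the somatostatin gene sst1.1 (11.2-fold lower). The other sox1a probe sets fell by less (−1.11 and −0.36). Of 8 genes of Rohon-Beard and other sensory neurons 5 fell, also when adjusted over the list alone (median −0.76, adjusted p = 1.35e-04, adjusted p = 0.129 with an estimated correlation). The transcription factor genes runx3 (−3.02, but −0.38 in its other probe set) and prdm14 (−2.10) led them. Motor neuron genes fell in 5 of 11 cases, also when adjusted over the list alone, among them etv4 (−1.42), isl2a (−1.12) and slc18a3a, the vesicular acetylcholine transporter (−0.68). Their median was −0.28, with adjusted p = 1.83e-03 and adjusted p = 0.129 with an estimated correlation. Of 5 genes of V0 and V3 interneurons 3 fell, nkx2.2b (−1.09), nkx2.2a (−0.79) and evx1 (−0.69), also when adjusted over the list alone (adjusted p = 1.40e-03, adjusted p = 0.131 with an estimated correlation). Of 12 dorsal interneuron genes, tlx3b (−1.73), tlx2 (−1.59) and dmrt3a (−1.20) fell and foxd3, which the V1 and neural crest lists also hold, rose (1.28), also when adjusted over the list alone. The dorsal list was lower as a set (median −0.07, adjusted p = 0.0398, adjusted p = 0.171 with an estimated correlation), a call that ended without all-neuron array 3 (adjusted p = 0.0562).

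Some neuropeptide and general neuronal genes also fell in V1 arrays. nppc, a natriuretic peptide precursor, had the largest decrease among the genes named by rule (13.7-fold lower, −3.78, SE 0.28, adjusted p = 2.34e-07), and scg2a, a secretogranin, was 9.82-fold lower (−3.30). Of 22 peptide precursor genes 11 fell and 1 rose, penkb (0.88), also when adjusted over the list alone (median −0.36, adjusted p = 9.74e-08, adjusted p = 0.13 with an estimated correlation). Of 41 postmitotic neuron genes 11 fell and 0 rose, also when adjusted over the list alone, with a median of −0.22 (adjusted p = 2.58e-05, adjusted p = 0.256 with an estimated correlation). The stathmin gene stmn4 (−2.17) and snap25b, part of the synaptic vesicle fusion machinery (−1.47), fell most. elavl3 did not pass the test in its brightest probe set (0.13, adjusted p = 0.736), but its next brightest probe set was lower in V1 arrays (−2.87, adjusted p = 6.94e-05). Of 18 ion channel genes 9 fell, also when adjusted over the list alone, such as the calcium channel gene cacna1ha (−1.34) and the potassium channel gene kcnd3 (−1.19). That set gave adjusted p = 2.58e-05, and adjusted p = 0.122 with an estimated correlation. Of 19 transmitter receptor genes 3 fell and 1 rose, also when adjusted over the list alone, and both probe sets of the glycine receptor gene glra4a fell (−2.24 and −2.09), while gria2b, an AMPA receptor subunit gene, rose (0.42). The acetylcholine receptor genes chrna1 (−1.33) and chrnb3a (−0.49) also fell, but lost their calls when single arrays were left out. This held for chrna1 without all-neuron array 1, 2 or 3 or V1 array 5 or 6 (adjusted p between 0.0519 and 0.0697), and for chrnb3a without all-neuron array 1, 4 or 5 or V1 array 1 or 2 (0.0509 to 0.0722). chrna1 and the ion channel gene cacng1a, which fell too (−1.43), are also in the skeletal muscle list. Like the muscle genes, chrna1 was higher in all-neuron arrays 1 to 3 (6.83, 7.39 and 6.88) than in arrays 4 and 5 (4.87 and 5.07), so its fall is not read as one of neurons. The receptor set gave adjusted p = 0.0119, and adjusted p = 0.235 with an estimated correlation. cbln1, a synapse organizer outside the lists, was 7.45-fold lower (−2.90).

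Progenitor genes fell in 19 of 49 cases and rose in 4 (21 and 4 adjusted over the list alone), with a median of −0.39 (adjusted p = 3.80e-06, adjusted p = 0.224 with an estimated correlation). shha, the Sonic hedgehog gene of floor plate and notochord (−2.33), sox19b (−2.20, but −0.26 in its other probe set, which did not pass) and the motor neuron progenitor factor olig2 (−1.90) fell. The sox19b probe set that fell read 6.81, 6.98, 5.05 and 5.27 in trunk arrays 1 to 4, a split as in AFFX-Dr-U43284-1_s_at. The 4 that rose were her9 (0.98), zic1 (0.88), notch2 (0.88) and her6 (0.67). Of 18 proneural and Delta genes neurod6a rose (0.29) and insm1b (−1.13), dla (−0.92), neurod4 (−0.75) and btg2 (−0.46) fell, also when adjusted over the list alone. That set was lower with adjusted p = 0.0486 (adjusted p = 0.347 with an estimated correlation). The call ended without all-neuron array 1, 2 or 3 or without V1 array 1, 4 or 6, left out singly, with adjusted p between 0.0623 and 0.0905. Of 60 genes of DNA replication and mitosis, orc6 rose (1.26) and nusap1 (−0.69), ccna2 (−0.50) and tk1 (−0.27) fell, or 1 and 1 adjusted over the list alone. This set was not called (adjusted p = 0.179), but came below the threshold without all-neuron array 4 (adjusted p = 0.0107) or 5 (0.0482) or V1 array 2 (0.0322).

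Markers of cells outside the nervous system differed in both directions between V1 and all-neuron arrays. The embryonic globin genes hbbe3 and hbae3 were 78.5-fold and 58.6-fold higher in V1 arrays (log2 differences 6.29, SE 0.28, adjusted p = 8.95e-10 and 5.87, SE 0.24, adjusted p = 3.85e-10), at 11.54 ± 0.66 against 5.25 ± 0.37 for hbbe3. The other hbae3 probe set was 25.8-fold higher. Further genes of the rule's 10 largest increases were aqp1a.1, a water channel of red cells and vessels, the vessel gene mrc1a and aqp8a.1. They read 8.54 to 10.14, 6.87 to 9.18 and 7.58 to 9.83 in V1 arrays, and 4.13 to 4.52, 3.77 to 4.25 and 4.03 to 4.38 in all-neuron arrays. The red cell anion exchanger gene slc4a1a, at 6.87 to 8.72 in V1 and 2.32 to 3.03 in all-neuron arrays, and yrk, at means of 7.44 and 3.43, were also among them. The low levels of these further genes are not known to lie above background, so no fold or place in the order is given. Of 33 blood and vessel genes 24 rose and 2 fell (25 and 2 adjusted over the list alone; median 1.45, adjusted p = 1.35e-13, adjusted p = 0.112 with an estimated correlation). The 2 that fell, gata2a (−1.66) and tal1 (−1.80), are also in the V2 list. dct, a melanin synthesis enzyme gene, was 29.8-fold higher (4.90, SE 0.29, adjusted p = 1.63e-08), and mitfa, the melanocyte master regulator, 10.4-fold (3.38). crestin, a neural crest transcript, was 8.59-fold higher. Of 21 neural crest and pigment genes 15 rose and 0 fell (17 and 0 adjusted over the list alone; median 1.09, adjusted p = 2.17e-11, adjusted p = 0.0241 with an estimated correlation).

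Pronephros genes, which the labels' removal of the pronephros region for V1 samples bears on, rose in 14 of 33 cases and fell in 3 (14 and 4 adjusted over the list alone). Pronephros cells also carry pax2a, whose control sequence drives the V1 reporter. The list means were 5.94 in V1, 5.23 in all-neuron and 5.53 in trunk arrays. The ion transport genes slc4a2a (4.41) and atp1a1a.4 (4.37) and the water channel gene aqp3a (9.97-fold, 3.32) rose most in signal, and gata3, irx1b (−0.62) and rfx2 (−0.61) fell. No fold is given for slc4a2a, at 3.93 to 5 in all-neuron arrays, or atp1a1a.4, since their low levels are not known to lie above background. The other slc4a2a probe sets differed by 0.55 and 0.08, and the latter did not pass. atp1a1a.4 read 8.75 on all-neuron array 1 and 3.98 to 4.24 on the other all-neuron arrays, and its difference was 5.30 without that array. The list was higher as a set (median 0.08, adjusted p = 0.0227, adjusted p = 0.202 with an estimated correlation). With ribosomal protein means set equal its median was −0.48, beside −0.57 for all probe sets. Of 46 skin genes 10 rose and 1 fell (12 and 1 adjusted over the list alone), such as elf3 (2.43) and the keratin gene krt8 (2.06), and the set was not called (median 0.01, adjusted p = 0.303).

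Skeletal muscle genes fell in 30 of 56 cases and rose in 1, tpm3 (0.64), or 37 and 1 adjusted over the list alone (median −1.02, adjusted p = 1.84e-11, adjusted p = 0.235 with an estimated correlation). The contractile genes tnni2a.4 (−2.37), pvalb2 (−2.31) and mylpfa (−2.29) fell most. Against all-neuron arrays 4 and 5 alone, a choice made after the data were seen, the muscle median was −0.09 and the set was not called (adjusted p = 0.0693). Notochord and floor plate genes fell in 15 of 30 cases and rose in 2, the laminin genes lamb1a (1.24) and lama4, or 16 and 2 adjusted over the list alone. Their median was −0.34, with adjusted p = 4.05e-06 and adjusted p = 0.126 with an estimated correlation. The cartilage and notochord collagen genes col9a1b (8.43-fold lower, −3.07), col9a3 (7.41-fold lower, −2.89), col9a2 (−2.85) and col2a1a (−2.35) fell. copb2 was lower in 1 probe set (−3.46, SE 1.1, adjusted p = 0.0308) and less so in its other probe sets (−0.47 and −0.76). The first is a mean that no array shows, since all-neuron arrays 1, 4 and 5 read 8.02, 8.73 and 8.79 but arrays 2 and 3 read 3.33 and 3.47, beside 2.69 to 3.26 in V1 arrays. It lost its call without V1 array 4 (−3.40) or 5 (−3.44) or all-neuron array 1 (−3.07), 4 (−2.89) or 5 (−2.88), and was −4.25 without all-neuron array 2.

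Ribosomal protein genes rose in 66 of 72 cases and 0 fell (71 and 0 adjusted over the list alone), as for rpl12 (1.93-fold) and rpl29 (1.85-fold). Their means were 11.85 ± 0.22 (SD, n = 6) in V1 arrays and 11.28 ± 0.16 (n = 5) in all-neuron arrays. The set had a median of 0.56 (adjusted p = 2.51e-20, adjusted p = 0.202 with an estimated correlation). Hox genes fell in 6 of 42 cases and rose in 1, also when adjusted over the list alone, and the set was lower (median −0.14, adjusted p = 4.84e-03, adjusted p = 0.235 with an estimated correlation). hoxc6b (−0.84) and hoxa11b (−0.76) fell, and hoxc11a rose in 1 probe set (0.65) but not in its others (−0.04 and 0.31). Of 46 axon guidance genes 3 rose, such as cxcr4a (1.53), and 7 fell, such as sema3e (−1.11) and ntng1a (−1.10), also when adjusted over the list alone, with no call for the set (adjusted p = 0.121). Of 46 stress and immediate early genes 10 rose, such as cebpd (2.12, but 0.03 in its dim other probe set) and gadd45aa, at 4.77 to 5.92 against 3.02 to 3.39 near the bottom of the scale, and 6 fell (12 and 7 adjusted over the list alone), with adjusted p = 0.612 for the set. Of 87 genes of oxidative phosphorylation 6 rose and 3 fell (3 and 1 adjusted over the list alone), such as cox4i2 (0.66), atp5if1a (0.60) and ndufa4b (−1.35), with adjusted p = 0.691 for the set. Of 11 sterol synthesis genes 2 fell, also when adjusted over the list alone, fdps (−0.63) and dhcr7 (−0.73). The call of dhcr7 ended without all-neuron array 3, 4 or 5 or V1 array 4, 5 or 6, left out singly (adjusted p between 0.0616 and 0.0859). The sterol set was not called (adjusted p = 0.0701), but came below the threshold without all-neuron array 1 (0.0413) or 2 (0.0303).

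**Figure D1:**
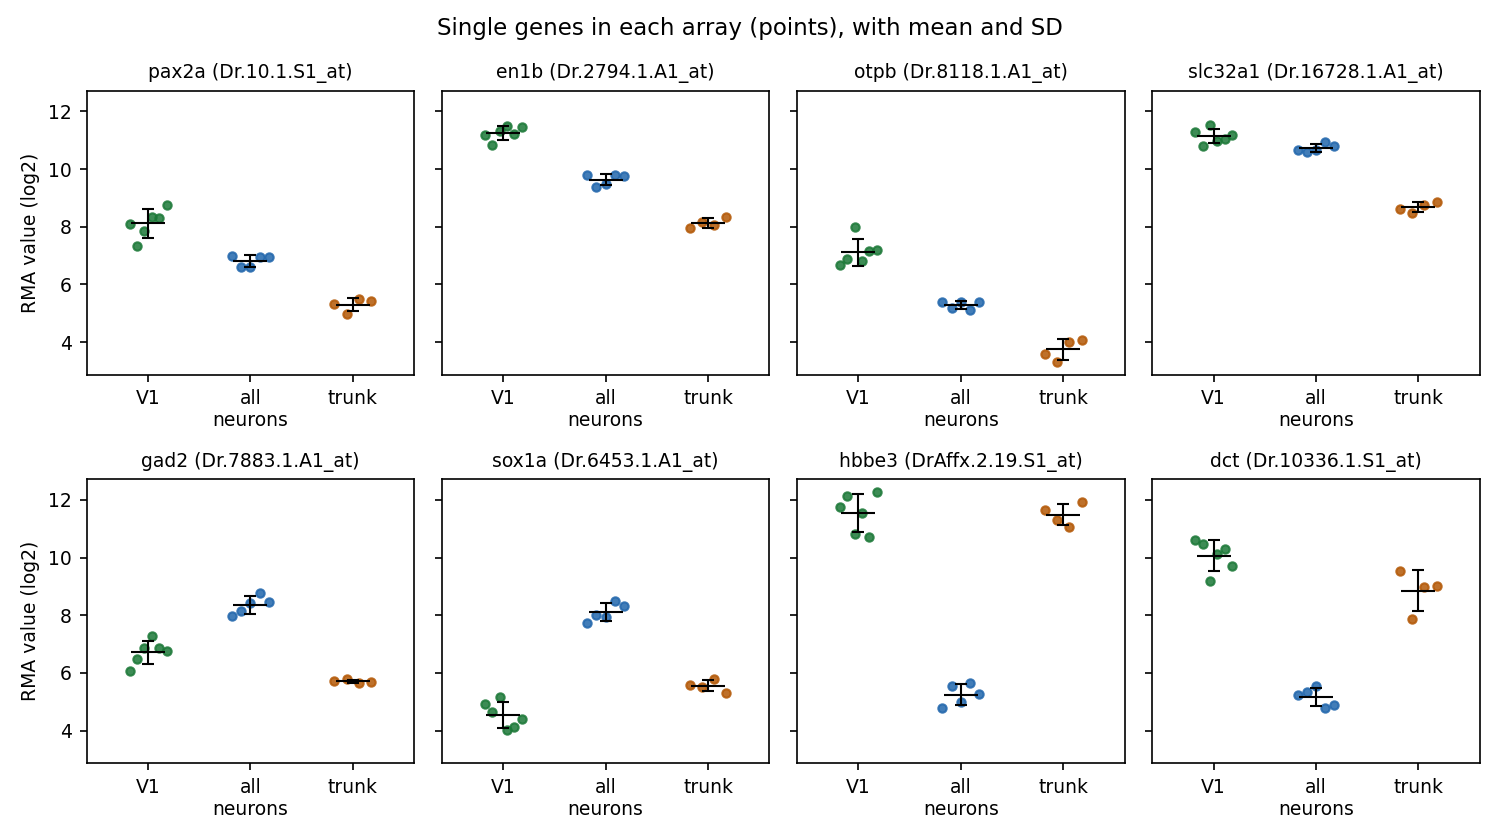
RMA values (log2, vertical axis) of 8 genes in V1, all-neuron and trunk arrays (horizontal axis), with each array as a point and the group mean and SD as a bar. pax2a, en1b and otpb were highest in V1 arrays, gad2 and sox1a in all-neuron arrays, and hbbe3 had means of 11.54 in V1, 5.25 in all-neuron and 11.49 in trunk arrays. slc32a1 stood higher in V1 than in all-neuron arrays by 0.41. With ribosomal protein means set equal it stood at −0.15, while the median of all probe sets moved to −0.57.

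**Figure D2:**
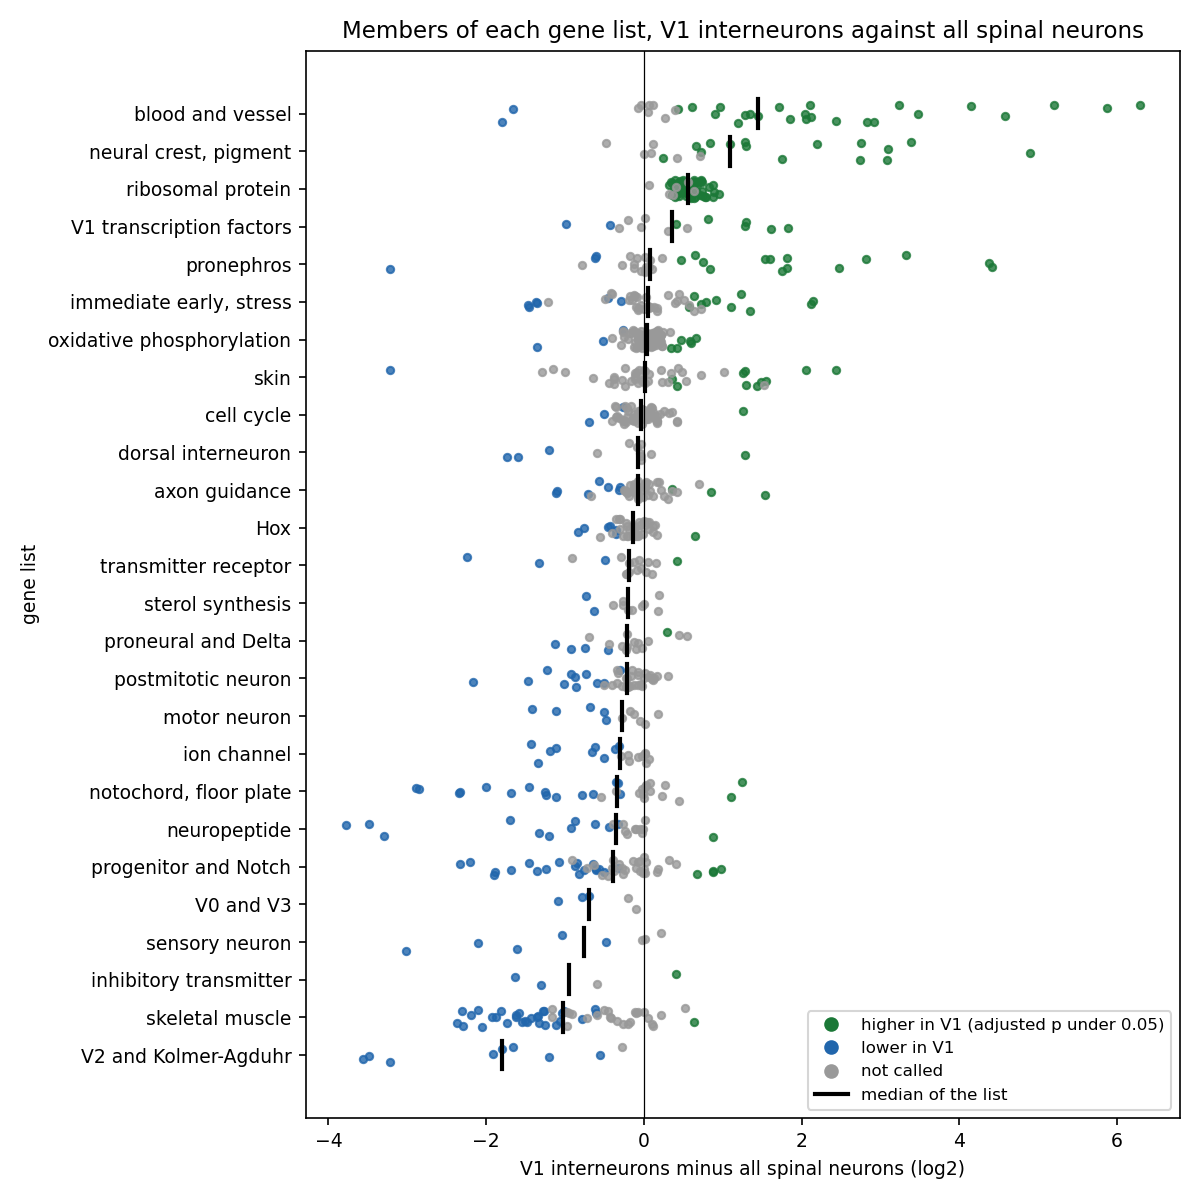
Log2 difference between V1 and all-neuron arrays (horizontal axis) for each measured member of 26 gene lists (vertical axis), in green where higher, in blue where lower and in grey where not called, with a black bar at the list's median. Medians were 1.45 for blood and vessel and 1.09 for neural crest and pigment genes but −1.80 for V2 and Kolmer-Agduhr genes. Those of the V1 transcription factors (0.36) and pronephros (0.08) were smaller. Setting ribosomal protein means equal moved all probe sets down alike (median −0.57), which turned these last medians negative.

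The next comparison set V1 interneurons against the trunk cells that surround them. V1 arrays held more transcript of some V1 transcription factors and many neuronal genes, and far less of most skeletal muscle genes. otpb was higher (adjusted p = 1.66e-08), at 6.66 to 7.98 against 3.32 to 4.08 near the bottom of the scale, so no fold is given. en1b was 8.70-fold higher at 11.25 ± 0.24 (SD, n = 6) against 8.13 ± 0.16 (n = 4). The V1 reporter's gene pax2a was 7.06-fold higher (2.82), though its other probe set did not pass (0.17, adjusted p = 0.236). The homeobox genes hmx3a (log2 difference 3.33) and lhx5 (3.08), the enkephalin precursor gene penkb (3.18) and the neurexin gene nrxn1a (2.91) were also higher. The sarcomere gene myoz1b was 46.3-fold lower (−5.53, SE 0.35, adjusted p = 1.95e-08). pvalb2 (33.4-fold), the mitochondrial carrier gene slc25a4 (33.1-fold) and mybpc2b (32.4-fold) were also lower. So were chrne, a muscle acetylcholine receptor subunit, and cacng1a, at 9.36 to 10 and 9.06 to 9.69 in trunk arrays. Their V1 levels, 3.91 to 5.14 and 3.60 to 5.25, are not known to lie above background, so no fold is given. Of 15502 probe sets 3411 were higher and 2797 lower in V1 arrays, and 967 and 721 of these differed by a log2 difference of 1 or more. With ribosomal protein means set equal the median of all probe sets moved to −0.11 and the split to 2132 higher and 2309 lower.

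The V1 transcription factor list had 8 of 14 members higher and 2 lower than in trunk, sp8b (−0.87) and en1a, near the bottom of the scale in both groups (−0.57), also when adjusted over the list alone (median 0.68, adjusted p = 2.17e-03, adjusted p = 0.31 with an estimated correlation). Genes named here and in the next paragraph beyond the rule were chosen after their values were seen. Postmitotic neuron genes rose in 33 of 41 cases and 0 fell, also when adjusted over the list alone (median 1.39, adjusted p = 7.88e-15, adjusted p = 0.31 with an estimated correlation). They included syt1a, a synaptic vesicle calcium sensor (2.40), and elavl3 (1.69, adjusted p = 3.34e-05). The next brightest elavl3 probe set did not pass (0.26, adjusted p = 0.649). slc32a1 (2.47), gad1b (1.36) and gad2 (1.01) all rose, 3 of 4 measured inhibitory genes, also when adjusted over the list alone, with adjusted p = 0.014 for the set and adjusted p = 0.325 with an estimated correlation. Hox genes rose in 17 of 42 cases and 1 fell, hoxc13a (−0.28), or 18 and 1 adjusted over the list alone, with hoxd11a at 1.75. The Hox median was 0.35, with adjusted p = 8.51e-04 and adjusted p = 0.325 with an estimated correlation. Genes of V2 interneurons and Kolmer-Agduhr cells fell in 6 of 9 cases, also when adjusted over the list alone, with gata3 and sox1a both at −1.01 and a median of −0.43 (adjusted p = 0.045, adjusted p = 0.605 with an estimated correlation). That call ended without V1 array 5 (adjusted p = 0.0508), trunk array 3 (0.0756) or trunk array 4 (0.0587).

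Skeletal muscle genes fell in 52 of 56 cases and 0 rose (52 and 1 adjusted over the list alone). Their list means were 6.43 ± 0.29 (SD, n = 6) in V1 and 9.72 ± 0.11 (n = 4) in trunk arrays (median −3.64, adjusted p = 3.15e-28, adjusted p = 0.31 with an estimated correlation). Blood and vessel genes stood at a like level in both groups, 6.55 ± 0.33 and 6.58 ± 0.20. Of these genes 4 rose, led by aqp8a.1 (1.44), and 3 fell, lcp1 (−1.55), sptb (−1.52) and cpa5 (−0.70), also when adjusted over the list alone (median −0.04, adjusted p = 0.867). Neural crest and pigment genes rose in 11 of 21 cases and fell in 3 (12 and 3 adjusted over the list alone), with mitfa at 1.75 and the mesenchyme gene foxc1b at −1.37. There was no call for the set (median 0.56, adjusted p = 0.0647) except without V1 array 3 (adjusted p = 0.0262). Pronephros genes rose in 11 of 33 cases, such as ret (2.21), and fell in 2 (12 and 2 adjusted over the list alone), without a call for the set (median 0.02, adjusted p = 0.2). Among those named against all neurons, aqp3a had means of 9.38 in V1 and 7.55 in trunk arrays, and atp1a1a.4 of 9.40 and 7.50. Notochord and floor plate genes fell in 13 of 30 cases, also when adjusted over the list alone (median −0.41, adjusted p = 7.64e-04, adjusted p = 0.325 with an estimated correlation), with col9a3 at −2.88. Skin genes fell in 20 of 46 cases and rose in 4 (21 and 4 adjusted over the list alone; median −0.40, adjusted p = 0.0134, adjusted p = 0.672 with an estimated correlation). The annexin gene anxa1c stood at −3.25 and elf3 at 1.67. Of 87 oxidative phosphorylation genes 71 fell and 1 rose, cox6b1 (1.08), or 75 and 1 adjusted over the list alone (median −0.60, adjusted p = 2.01e-15, adjusted p = 0.325 with an estimated correlation). Ribosomal protein genes rose in 4 of 72 cases and fell in 2 (1 and 1 adjusted over the list alone), with a median of 0.09 that cyclic loess scaling turned to −0.25 (adjusted p = 0.258 and 6.11e-05). The set came below the threshold without V1 array 4 (adjusted p = 0.0269) or trunk array 1 (0.0365). The axon guidance set, not called (adjusted p = 0.689), had a median of −0.05 but a mean of 0.09 and a test statistic on the higher side.

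The remaining comparison asked which transcripts spinal neurons as a whole carry at another level than trunk cells. All-neuron arrays held more transcript of many neuronal and Hox genes and of some spinal cell class genes, and less of many blood, muscle, pigment and energy metabolism genes. ndrg4 was 5.11-fold and elavl3 2.95-fold higher in its brightest probe set. A further probe set of each was also higher, but no fold is given, since trunk arrays 1 to 4 were unlike. They read 3.40, 3.32, 5.07 and 5.38 for ndrg4 and 7.51, 7.11, 4.62 and 5.20 for elavl3. Also higher were sypb, a synaptic vesicle protein gene (7.65-fold), sncgb, a synuclein gene (7.60-fold), maptb, a microtubule binding protein gene (7.54-fold), and nppc (7.15-fold). Dimmer probe sets of sypb (0.33) and sncgb (0.07 and −0.01) did not pass. hbbe3 was 75.7-fold lower at 5.25 ± 0.37 (SD, n = 5) against 11.49 ± 0.37 (n = 4), with hbae3 45.0-fold lower (log2 difference −4.60 in its other probe set). aqp1a.1 and chrne were lower too, at 4.13 to 4.52 and 4.01 to 5.97 in all-neuron arrays. These levels are not known to lie above background, so no fold is given. slc4a1a, at 7.48 to 8.57 in trunk arrays, and cahz, a red cell carbonic anhydrase gene, at 6.97 to 8.09, were also lower. Both stood near the bottom of the scale in all-neuron arrays (2.32 to 3.03 and 3.35 to 3.44), so no fold is given. Of 15502 probe sets 3219 were higher and 3196 lower, and 1156 and 1151 of these differed by a log2 difference of 1 or more. With ribosomal protein means set equal the median of all probe sets moved to 0.45 and the split to 8652 higher and 1255 lower.

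Postmitotic neuron genes rose in 36 of 41 cases (37 adjusted over the list alone). Their means were 8.91 ± 0.19 (SD, n = 5) and 7.38 ± 0.18 (n = 4), with a median difference of 1.68 (adjusted p = 8.66e-20, adjusted p = 0.132 with an estimated correlation). All 4 inhibitory genes rose, among them gad1b and gad2, both by 2.65, also when adjusted over the list alone (adjusted p = 4.94e-04, adjusted p = 0.132 with an estimated correlation). Of the V1 transcription factors 7 of 14 rose, such as lhx5 (2.27), lhx1a (1.92), pax2a (1.52, but −0.12 in its other probe set, which did not pass) and en1b (1.51). Only en1a was called lower (−0.53), between levels near the bottom of the scale (2.74 to 3.15 against 3.33 to 3.77), and the counts were the same when adjusted over the list alone (adjusted p = 3.16e-03, adjusted p = 0.173 with an estimated correlation). V2 and Kolmer-Agduhr genes rose in 8 of 9 cases, such as sst1.1 (2.63) and sox1a (2.55, but −0.05 in 1 other probe set). Motor neuron genes rose in 7 of 11 cases, such as isl2a (2.49) and isl1a (2.34), and sensory neuron genes in 7 of 8, such as prdm14 (2.63). In these 3 lists the counts were the same when adjusted over the list alone. These 3 sets gave adjusted p = 1.16e-05, 4.94e-04 and 9.83e-05, each with adjusted p = 0.132 with an estimated correlation. V0 and V3 genes rose in 3 of 5 cases (adjusted p = 0.0521) and dorsal interneuron genes in 4 of 12 (median 0.03, adjusted p = 0.118), also when adjusted over the list alone, without a call for either set. Peptide precursor genes rose in 13 of 22 cases, also when adjusted over the list alone (adjusted p = 1.69e-05, adjusted p = 0.201 with an estimated correlation). Ion channel genes rose in 10 of 18 cases, such as hcn2b (2.30), and 2 fell, also when adjusted over the list alone (adjusted p = 0.0119, adjusted p = 0.233 with an estimated correlation). Hox genes rose in 27 of 42 cases and 0 fell, also when adjusted over the list alone, such as hoxd11a (1.69) and hoxa10b (1.67), with adjusted p = 4.33e-07 and adjusted p = 0.132 with an estimated correlation. Progenitor genes rose in 15 of 49 cases and fell in 3, notch2 (−1.64), her9 (−1.05) and her6 (−0.59), also when adjusted over the list alone (adjusted p = 7.77e-03, adjusted p = 0.44 with an estimated correlation).

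Blood and vessel genes fell in 26 of 33 cases and rose in 2, gata2a (1.48) and tal1 (1.43), also when adjusted over the list alone (median −2.08, adjusted p = 4.86e-08, adjusted p = 0.173 with an estimated correlation). Skeletal muscle genes fell in 52 of 56 cases, also when adjusted over the list alone (median −2.59, adjusted p = 6.67e-17, adjusted p = 0.195 with an estimated correlation), such as cacng1a (−3.73) and klhl41b (−3.81). Neural crest and pigment genes fell in 11 of 21 cases (12 adjusted over the list alone), such as dct (−3.69) and foxc1a (−2.96), with adjusted p = 6.17e-04 and adjusted p = 0.173 with an estimated correlation. Skin genes fell in 28 of 46 cases and 1 rose, also when adjusted over the list alone (adjusted p = 1.01e-03, adjusted p = 0.36 with an estimated correlation). Pronephros genes fell in 9 of 33 cases and rose in 6 (12 and 6 adjusted over the list alone), without a call for the set (adjusted p = 0.663). slc4a2a fell by 2.76 in 1 probe set and did not differ in its others (0.03 and 0.03), and atp1a1a.4 fell by 2.47, or by 3.40 without all-neuron array 1. Oxidative phosphorylation genes fell in 74 of 87 cases and rose in 2, cox6b1 (1.48) and ndufa4b (1.07), or 78 and 2 adjusted over the list alone (median −0.64, adjusted p = 1.30e-13, adjusted p = 0.217 with an estimated correlation). Ribosomal protein genes fell in 55 of 72 cases (59 adjusted over the list alone), such as rpl7l1 (−1.27), with a median of −0.45 (adjusted p = 1.14e-07, adjusted p = 0.417 with an estimated correlation) that became 0.02 with their means set equal. Stress genes fell in 19 of 46 cases and rose in 2, ier5 (0.39) and dusp2 (0.76), also when adjusted over the list alone, led by the heat shock genes hsp90aa1.1 (11.4-fold lower) and hspb1 (5.49-fold lower). Like the muscle genes, both were lower in all-neuron arrays 4 and 5 (6.58 and 6.80 for hsp90aa1.1, 6.92 and 7.01 for hspb1) than in arrays 1 to 3 (8.46 to 8.94 and 8.18 to 8.46). The stress set had a median of −0.32 (adjusted p = 0.0126, adjusted p = 0.398 with an estimated correlation). With ribosomal protein means set equal it was 0.15, still below the median of all probe sets under that scaling (0.445).

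**Figure D3:**
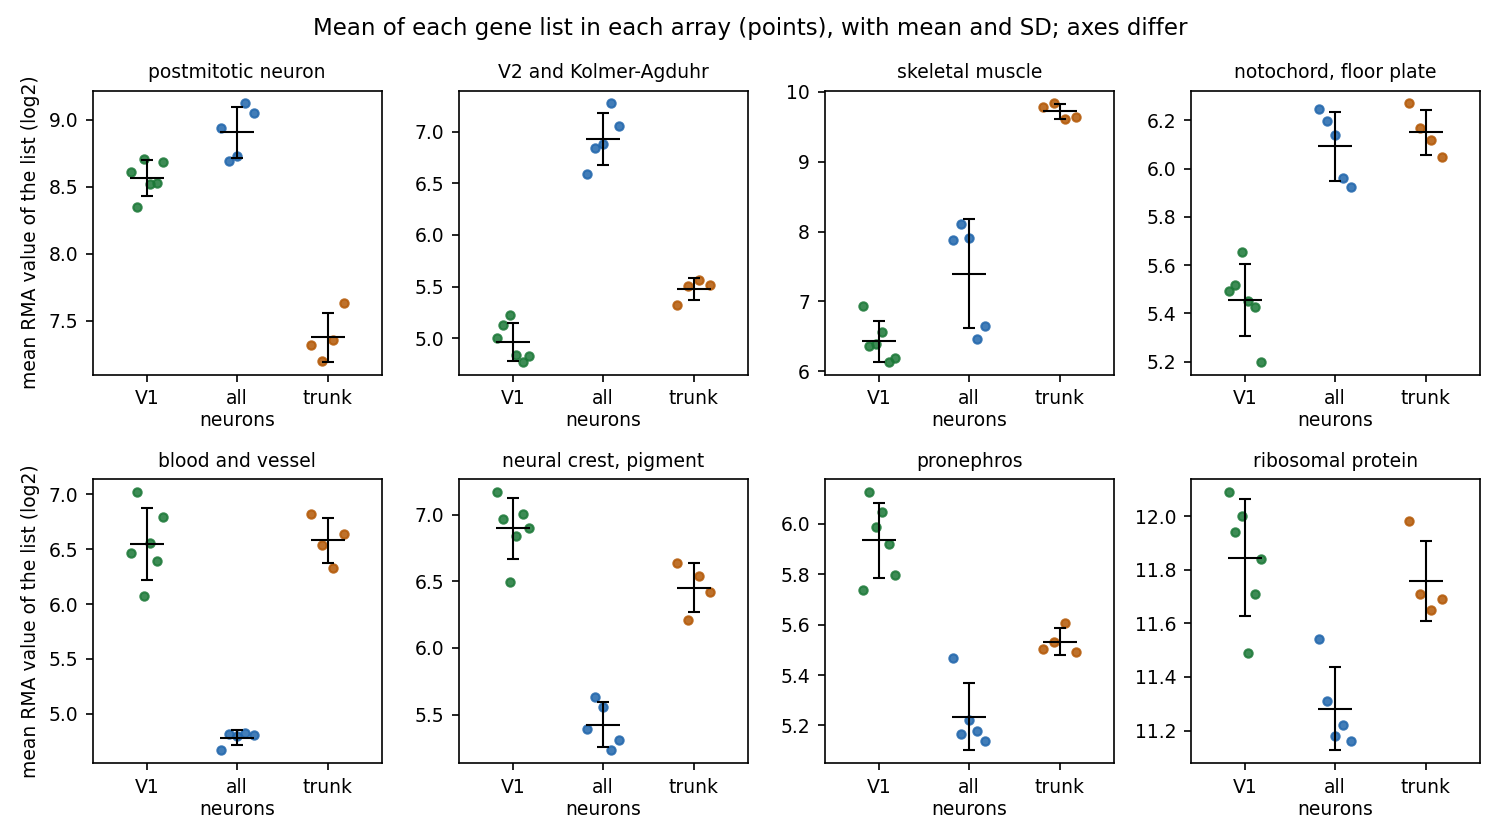
Mean RMA value (log2, vertical axis, with its own range in each panel) of the members of 8 gene lists on each array (points), by group (horizontal axis), with the group mean and SD as a bar. Blood and vessel genes had means of 6.55 in V1, 4.78 in all-neuron and 6.58 in trunk arrays, skeletal muscle genes 6.43, 7.40 and 9.72, and ribosomal protein genes 11.85, 11.28 and 11.76, where the last group's differences vanish by construction when its means are set equal.

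V1 arrays stood above both other populations in 748 probe sets, which stand for 520 genes, among them en1b, pax2a, otpb, foxd3, slc32a1 and mitfa. Both comparisons use the same V1 arrays, so an overlap arises from shared arrays too. Independent lists of the same sizes would share 433 probe sets, and unchanged groups simulated 100 times against shared V1 arrays gave a median of 0 and at most 0. The simulated groups hold no effects, so nearly no calls, and do not show what shared arrays add where effects exist. With the V1 arrays divided so that each comparison used different arrays, the overlap was 497 and 398. These fits used fewer V1 arrays, whereas the 433 holds for the full lists, so the counts are not to be set against it. Of the 1966 probe sets higher in V1 than in all-neuron arrays, 976 did not differ from trunk and 242 were lower than in trunk. V1 arrays stood below both populations in 401 probe sets, among them sox1a, gata3, col9a3 and glra4a, against 260 for independent lists and at most 1 in the simulations. With the arrays divided these were 182 and 199, which for the same reason are not to be set against the 260.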

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

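The tests on the elavl3 probe sets, and those on control probe set AFFX-Dr-U43284-1_s_at and on the DapX, LysX, PheX and ThrX control probe sets, were chosen only after the result was seen. The search for arrays far from the rest of their group covered 363 combinations of a named gene and a group and found 12, where chance, at about 1 in 20 groups, would give about 18. All-neuron array 1 read 8.75 for atp1a1a.4 where the other arrays of its group read 3.98 to 4.24, 7.62 for atp5if1a (others 7.13 to 7.23), 9.53 for rpl27a (others 8.44 to 8.73) and 8.18 for foxd3 (others 8.44 to 8.54). V1 array 3 read 11.15 for slc18a3a (others 10.66 to 10.76) and 5.27 for foxa2 (others 4.01 to 4.44). V1 array 6 read 6.49 for col2a1a (others 7.41 to 7.92), and V1 array 1 read 6.07 in the next brightest probe set of elavl3 (others 6.36 to 6.49). Trunk array 2 read 8.05 for copb2 (others 2.97 to 3.74) and 5.43 for yrk (others 6.87 to 7.08), trunk array 1 read 8.18 for fgf13a (others 8.47 to 8.51), and trunk array 4 read 6.24 for lhx1a (others 6.42 to 6.45).

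A signal also appeared in control probe sets outside the comparisons. AFFX-Dr-AF292560-1_s_at had a mean of 8.45 ± 0.52 (SD, n = 6) in V1 arrays, where single arrays read 7.48 to 8.91, against 3.23 ± 0.07 in all-neuron and 3.29 ± 0.08 in trunk arrays. AFFX-Dr-M62653-1_at had a mean of 5.63 ± 0.41 in V1 arrays, 3.01 ± 0.12 in all-neuron and 2.98 ± 0.13 in trunk arrays. AFFX-Dr-pd2EGFP_at read 6.30 ± 0.17, 6.40 ± 0.12 and 6.48 ± 0.12. AFFX-Dr-U43284-1_s_at had a mean of 10.43 ± 0.22 (n = 5) in all-neuron arrays and 5.29 ± 0.25 in V1 arrays, and read 8.02, 8.16, 5.63 and 5.71 in trunk arrays 1 to 4. Of 12 control probe sets of the DapX, LysX, PheX and ThrX names, 11 were higher in V1 than in all-neuron arrays, with a median of 1.65 (0.47 to 1.89), and 11 higher than in trunk arrays. Between all-neuron and trunk arrays 0 of these 12 were called, with a median of 0. What these control probe sets measure is not given in the sources used here, and the cause of their differences was not tested. Whether that cause also moved other probe sets in the V1 comparisons was not tested either.

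The probe sets of elavl3 disagreed between V1 and all-neuron arrays, with −2.87 in the next brightest against 0.13 in the brightest and 0.15 and 0.18 in dimmer ones. A shorter amplified product in the V1 samples is argued against by control probe sets for both ends of a transcript, where the difference of AFFX-Dr-GAPDH-5_at and AFFX-Dr-GAPDH-3_at was −3.49 ± 0.20 in V1 and −3.35 ± 0.16 in all-neuron arrays, a change of −0.14. The acta1 pair of control probe sets was unlike it, at −5.44 ± 0.52 in V1 and −6.89 ± 0.84 in all-neuron arrays. That change of 1.45 cannot be read as one of product length. AFFX-Dr-acta1-3_at, of a muscle gene, was lower in V1 arrays (−1.28), as many muscle genes were, while AFFX-Dr-acta1-5_at differed little (0.16). Whether the next brightest probe set also reads a transcript of the elavl3 transgenic line stays open, and the difference of 0.26 between V1 and trunk arrays (adjusted p = 0.649) cannot tell. It averages unlike trunk arrays, at 7.51 and 7.11 against 4.62 and 5.20, which split as in AFFX-Dr-U43284-1_s_at. V1 arrays stood 1.46 above trunk arrays 3 and 4 in this probe set, beside 1.40 in the brightest. Against trunk arrays 1 and 2 they stood at −0.94, beside 1.98 in the brightest. The labels name no line for any trunk array, so these values do not settle the question. A splice form of elavl3 at different levels in V1 and other neurons was not tested and also stays open.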

How the results depend on the processing

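All settings chosen beforehand were run, and those that leave out a set of arrays were chosen after seeing the data. Under the alternatives 390 counts of calls stayed within 1.5 times the reported count and 38 did not. Of counts at a log2 difference of 1 or more, 182 did and 10 did not. The cause of the changes below was not tested except where a filter tests fewer probe sets or a stricter threshold is met by fewer. With ribosomal protein means set equal, 498 probe sets were higher and 11760 lower in V1 than in all-neuron arrays, 2132 higher and 2309 lower in V1 than in trunk, 8652 higher and 1255 lower in all neurons than in trunk, and 184 in V1 above both. slc32a1 reversed in sign to −0.15 between V1 and all-neuron arrays, as this scaling moved all probe sets down alike (median −0.57). Keeping probe sets at or above the median left 1792 lower in V1 than in trunk. At the 75th percentile these counts were 943 and 606 (V1 against all neurons), 2032 and 1011 (V1 against trunk), 1771 and 1377 (all neurons against trunk) and 394 (above both). Testing against a log2 difference of 0.5 gave 390 and 236, 1017 and 714, 1266 and 1133, and 71. A threshold of 0.01 gave 1209 and 776 for V1 against all neurons, 1779 lower in V1 than in trunk, and 359 above both.

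Leaving out all-neuron arrays 4 and 5 gave 1239 probe sets higher and 945 lower in V1 than in all-neuron arrays. Leaving out arrays 1 to 3 gave 465 above both and reversed the set of replication and mitosis genes between V1 and all neurons to a median of 0.22. The mean of these genes was 7.597 to 7.666 in all-neuron arrays 1 to 3, but 7.072 and 7.236 in arrays 4 and 5. V1 arrays split alike, at 7.555 to 7.714 in arrays 1 to 3 and 6.994 to 7.274 in arrays 4 to 6, so the reversal compares unlike parts of the groups. Leaving out V1 arrays 1 to 3 reversed oxidative phosphorylation genes to −0.10, and leaving out trunk arrays 1 and 2 gave 1808 lower in V1 than in trunk. When single arrays were left out, no count moved by over 1.5 times. V1 against all neurons then gave 1583 to 2036 higher and 1130 to 1505 lower.

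Of the lists, cyclic loess called 7 higher and 8 lower in V1 than in trunk, and turned the ribosomal protein median there to −0.25. With the correlation estimated per list, 1 list was higher and 1 lower between V1 and all neurons, 0 and 0 between V1 and trunk, and 0 and 0 between all neurons and trunk. Where camera gave 0, lists with an unadjusted p under 0.05 numbered 2 higher and 1 lower between V1 and trunk, and 6 and 0 between all neurons and trunk. The fry test, which does not compare a list with other genes, called 9 higher and 6 lower in V1 than in trunk, and 13 and 7 between all neurons and trunk. Of list results 2439 were as reported, 91 lost and 107 gained a call, and 3 reversed. For named genes 4641 values were as reported, 97 lost and 1 gained a call, and 8 reversed. The reversals not yet given lie in other probe sets, which were elavl3 between V1 and all neurons (−2.87), hoxc11a (−0.04), and between all neurons and trunk pax2a (−0.12), slc4a2a (0.03 and 0.03), sncgb (−0.01) and sox1a (−0.05).

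Replicate numbers are shared between groups without a stated meaning. Of 13 pairs of arrays with the same number, 4 had a correlation of deviations over 0.1 (−0.135 to 0.356), and 5 of 12 arrays matched their own number best. With the number as a fixed block, 1742 and 1272 probe sets were called between V1 and all neurons, 2944 and 2174 between V1 and trunk, 3032 and 2879 between all neurons and trunk, and 565 above both. As a random block the first counts were 1935 and 1410. Array signal without detection calls limits what can be said of dim probe sets, such as en1a near 2.91.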

Other observations

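The tests of carry-over, of dilution and of other splits of the arrays were chosen only after the results were seen. Against trunk cells, V1 arrays also held more transcript of some genes of other neurons. Of 11 motor neuron genes 5 rose and 0 fell (5 and 1 adjusted over the list alone), with isl1a at 1.86, isl2a at 1.37 and slc18a3a at 1.14. The set was not called (adjusted p = 0.0544) but came below the threshold without all-neuron array 4, V1 array 2 or 6, or trunk array 2 or 4 (adjusted p between 0.0349 and 0.049). Of 22 peptide precursor genes 4 rose, penkb (3.18), scg5 (2.04), cpe (1.77) and chga (1.68), and 4 fell, nppc (−0.94), scg2a (−0.92), sst1.1 (−0.86) and urp2 (−0.43), also when adjusted over the list alone (adjusted p = 0.936). Of 12 dorsal interneuron genes 3 rose, such as dmrt3a (0.87), and 1 fell, and of 18 ion channel genes 4 rose and 4 fell, in both lists also when adjusted over the list alone. Genes named in this part beyond the rule were chosen after their values were seen.

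Of 46 stress genes 16 fell and 3 rose in V1 compared with trunk, also when adjusted over the list alone. Among them were hsp90aa1.1 (−4.73) and hspb1 (−3.81), which split as the muscle genes did among all-neuron arrays, and hsp90aa1.2 (1.87). The set was not called (median −0.38, adjusted p = 0.0532) but came below the threshold without all-neuron array 2, 4 or 5, V1 array 1, 2 or 5, or trunk array 3 or 4 (adjusted p between 0.0247 and 0.0484). Of 60 replication and mitosis genes 11 fell and 0 rose (3 and 0 adjusted over the list alone), with a median of −0.20 and adjusted p = 0.0564. That p came below the threshold without all-neuron array 4, V1 array 1, 2 or 3, or trunk array 2 or 3 (adjusted p between 0.0151 and 0.049). In all neurons compared with trunk, notochord and floor plate genes went both ways, with 6 higher, such as shha (1.71) and foxa2 (1.45), and 7 lower, such as p4ha1b (−1.41), also when adjusted over the list alone (adjusted p = 0.982).

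Blood, vessel, neural crest and pigment genes were higher in V1 than in all-neuron arrays, with hbbe3 at 11.54 and dct at 10.06 in V1 arrays. Carry-over of trunk cells at large is argued against by the skeletal muscle list, whose median lay −3.64 from trunk in V1 arrays while that of the blood list lay at −0.04. Over the 6 V1 arrays, the 24 blood and vessel and 15 crest and pigment genes that rose varied more with their own list (mean r 0.478 and 0.481) than with the other (0.273), a difference of 0.206 (one-sided permutation p = 1e-04, the smallest that the permutations of list labels can give). The permutations exchange genes, which are not independent replicates, so this p does not measure evidence between arrays. Cells of these types in the V1 samples, in shares that varied, could give such correlations. How fully the gate on GFP removed cells without the reporter was not tested. Joint regulation of each list within V1 cells and differences between the fish lines were not tested and stay open, and of the lists' members gata2a, tal1, foxd3, tfap2a and efnb2a are in other lists too.

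gad1b (−1.30) and gad2 (−1.63) were lower in V1 than in all-neuron arrays while slc32a1 was not. Dilution of neuronal RNA by other cells, as the whole cause, is argued against by the postmitotic neuron genes, whose median fell by 0.22 only (log2 difference −0.22). Lower levels of these transcripts in V1 cells than in other inhibitory neurons could also give this pattern. That biological explanation was not tested.

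Chance was examined with other splits of the arrays into groups of the same sizes. Of 100 splits, 1, the real one, called as many probe sets as the 3408 between V1 and all-neuron arrays, and the highest other called 1088. Between V1 and trunk arrays the real split called 6208 and the highest other 115, and again 1 of 100 splits called as many. Between all-neuron and trunk arrays 1 of 100 splits reached the real 6415, and the highest other, which puts a single all-neuron array with the trunk arrays and is otherwise the real one, called 4663. The 100 splits were drawn from 462, 210 and 126 possible ones, and no other split drawn reached the real count. Mixing unlike groups widens the spread within them, so few calls in such splits were likely beforehand. The splits also cannot tell the cell population from the fish line or other differences between the groups' samples.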
